A study of Rattus norvegicus with 16 samples.

How the data were processed

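Messenger RNA was sequenced from the ventral prostate of 16 rats (Rattus norvegicus), the offspring of dams fed a normal diet with 17% protein (CTR) or a low protein diet with 6% protein through gestation and lactation (GLLP). The glands were taken at postnatal day (PND) 21 or 540, frozen, and extracted with Trizol; a company prepared standard Illumina libraries from the total RNA, per the labels' protocols. The labels number the samples within each group, and nothing in them states which samples share a litter, so p-values measure the spread between these samples.

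The authors deposited raw read counts per gene in 2 tables, 1 for each age, and the counts are whole numbers that were not normalized. STAR, edgeR 3.34.0 and the genome build Rnor_6.0 are named in the submitters' processing notes, without their roles, and the counting tool, the annotation and the use of strand are not given in the sources used here. The PND21 table has 28688 entries, of which 6805 carry AABR clone names and 20452 hold at least 1 count. The PND540 table has 24218 entries, of which 4173 carry LOC names and 19714 hold counts. The tables share 19709 gene names and differ in the rest, so they were made with different gene annotations, and any difference in counting between them is part of every value that sets 1 age against the other. At PND21, 25 gene names looked like dates and 4 entries shared a name with another; they were kept apart and not named. Of the gene names, 17094 in the PND21 table and 17922 in the PND540 table matched symbols of the RefSeq annotation of GRCr8, which was used only for gene length. No coordinates are given, because that assembly is not the build named in the notes.

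Totals ran from 30529776 to 39161666 counts per library at PND21 and from 28748604 to 37587255 at PND540. Counts of replicate pairs differed far beyond sampling noise, with a chi-square per degree of freedom of 30.3 to 829, so no library was counted as a duplicate of another. Each comparison was fitted with edgeR 4.0.16 in R 4.3.3: filterByExpr on the groups, TMM normalization, robust quasi-likelihood fits and quasi-likelihood tests, with Benjamini-Hochberg adjustment and a threshold of 0.05. CPM values were computed from these counts with TMM-scaled library sizes, unless said otherwise. Each diet effect was fitted within its age (7 libraries at PND21, 9 at PND540). The age effects and the interaction used the genes named in both tables, with 9, 7 and 16 libraries. On simulated counts with 200 changed genes, the PND21 comparison (14721 genes tested) recovered 47.8% of genes changed 1.5-fold, 83.6% of those changed 2-fold and 97% of those changed 4-fold. The PND540 comparison (14540 genes) recovered 0%, 2.99% and 74.2% at the same sizes. The corresponding shares were 0%, 10.4% and 68.2% for the age effect in CTR (13388 genes), 0%, 29.9% and 90.9% for the age effect in GLLP (13522 genes), and 1.49%, 1.49% and 50% for the interaction (14010 genes). Unchanged genes were called in 16 cases for the PND21 comparison, 1 for the PND540 comparison, 2 for the age effect in CTR, 3 for the age effect in GLLP and 0 for the interaction.

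Before the data were examined, 30 gene lists were fixed for the cell types of the gland and its surroundings and for pathways that fit the tissue and the diet. Each list with at least 5 tested genes was tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01, two-sided, adjusted over 29 lists. Camera with an estimated correlation and fry were run beside it. The score of a list in a library is the mean log2 CPM of its tested genes, less their mean over the CTR libraries of that age. Genes were named by a rule also fixed beforehand: among genes past the threshold with a symbol that is not a clone name, a mean of at least 5 CPM in the higher group and groups that did not overlap (the last not asked for the interaction), the 8 with the largest fold change and the 5 with the smallest p in each direction. For each list the rule added the 4 tested members with the smallest p, called ones first, and every called member where 4 or fewer were called. Where no gene passed it took the 5 with the smallest p, and for the overlap of the ages every shared call if 10 or fewer. Genes named outside the rule are said to be so, and some list members that the rule takes are not reported here.

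Alternatives fixed beforehand were RLE size factors, library size alone, DESeq2 1.42.0, no filter, a filter at 1 CPM, non-robust dispersions, an added 2-fold threshold, a joint fit of all 16 libraries for the diet effects, a block for the replicate number, and leaving out each library in turn. Limma voom with sample quality weights, the PND21 fit without mitochondrial genes, and fits without a catalogue of 169 striated muscle genes were added after seeing the data; the catalogue too was written after the calls had been seen. Figures were drawn with matplotlib 3.10.9.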

Results

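The ventral prostate is an androgen-dependent gland whose epithelium secretes into the seminal fluid. Its transcriptome was measured at PND21 in 4 CTR and 3 GLLP offspring and at PND540 in 5 CTR and 4 GLLP offspring. The design asks what a maternal low protein diet does to the gland at each age, how the gland differs between the ages, and whether the diet effect depends on age. Totals per library lay between 28748604 and 39161666 counts.

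At PND21 the first principal component of log2 CPM took 38.9% of the variance and placed the 3 GLLP libraries on the other side of 0 from the 4 CTR libraries. CTR replicate 1 differed in its mitochondrial counts: 12 mitochondrial genes had 0 counts there, and mitochondrial genes held 0.282% of its counts against 3.66% to 5.02% elsewhere. At PND540 the first component took 52.9% of the variance and set CTR replicate 5 apart from the other 8 libraries. Its median correlation with them was 0.851, and that of every other PND540 library was at least 0.956. In CTR replicate 5, 10443 of 14767 tested genes (70.7%) lay outside the range of the other 8 libraries.

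**Figure D1:**
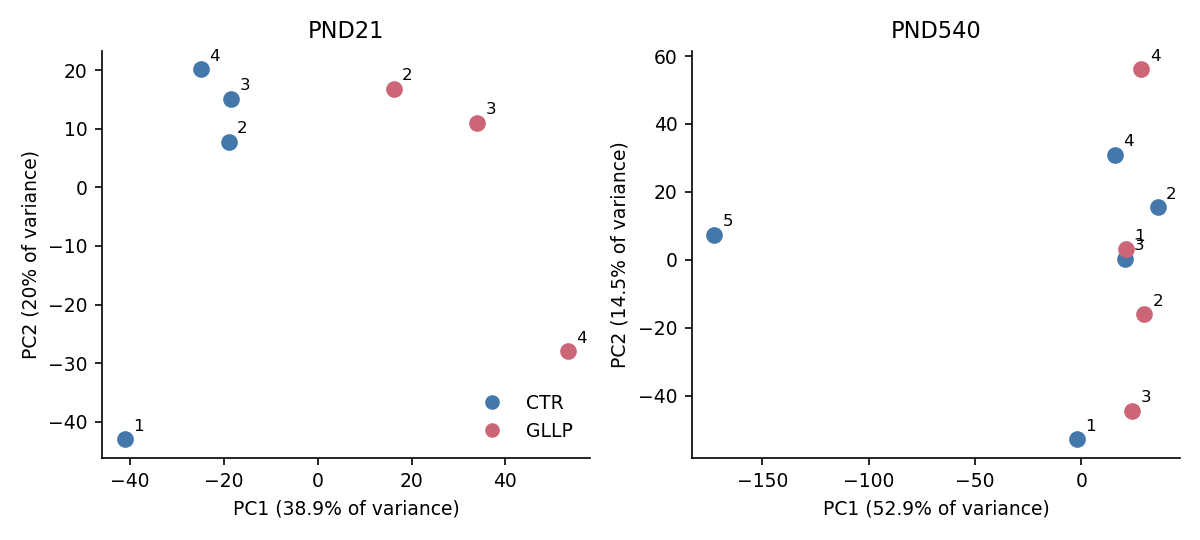
First and second principal components of log2 CPM for the PND21 libraries (left) and the PND540 libraries (right), with the share of variance on each axis; points are libraries, coloured by maternal diet and numbered by replicate. CTR replicate 5 at PND540 sits at -172.5 on the first component, far from the other 8 libraries.

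The diet comparison at PND21 was led by genes of skeletal muscle contraction and energy supply, which were far higher in every GLLP library. Myl1, a myosin light chain of fast fibres, rose from 0.159 ± 0.0838 CPM (SD, n = 4) in CTR to 53.8 ± 9.89 CPM (SD, n = 3) in GLLP, a log2 fold change of 8.36 (SE 0.28, adjusted p = 2.27e-06, edgeR). Muscle creatine kinase (Ckm) rose 50.8-fold, from 0.921 ± 0.161 to 47 ± 11.5 CPM, and the fast troponin I gene Tnni2 rose 54.6-fold. The fast myosin heavy chain Myh4 went from 1.36 ± 1.14 to 175 ± 81.7 CPM, the perinatal heavy chain Myh8 from 0.0283 ± 0.0566 to 7.44 ± 2.83 CPM, and myoglobin (Mb) from 0.058 ± 0.097 to 6.71 ± 3.69 CPM. Mylpf rose 17.5-fold, Mybpc1 40.1-fold, Nrap 121-fold and the fast-fibre actinin Actn3 37.9-fold.

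Of the 22 tested genes on the skeletal muscle list, 19 were called higher, 22 were called when adjusted over the list alone, and 21 had every GLLP library above every CTR library; chance leaves 5.71% of genes without overlap in either direction, and 17.1% of all tested genes had none. The median log2 fold change of the list was 3.98 (camera adjusted p = 3.2e-33, and adjusted p = 0.0311 with an estimated correlation). It was the only list whose call held with an estimated correlation. Skeletal actin (Acta1), named outside the rule after its values were seen, which already stood at 331 ± 37.3 CPM in CTR, rose 1.64-fold. Smooth muscle genes, which include the actin and myosin of the gland's own stroma, showed no such difference: none of 14 was called and their median was 0.00162 (camera adjusted p = 0.74).

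**Figure D2:**
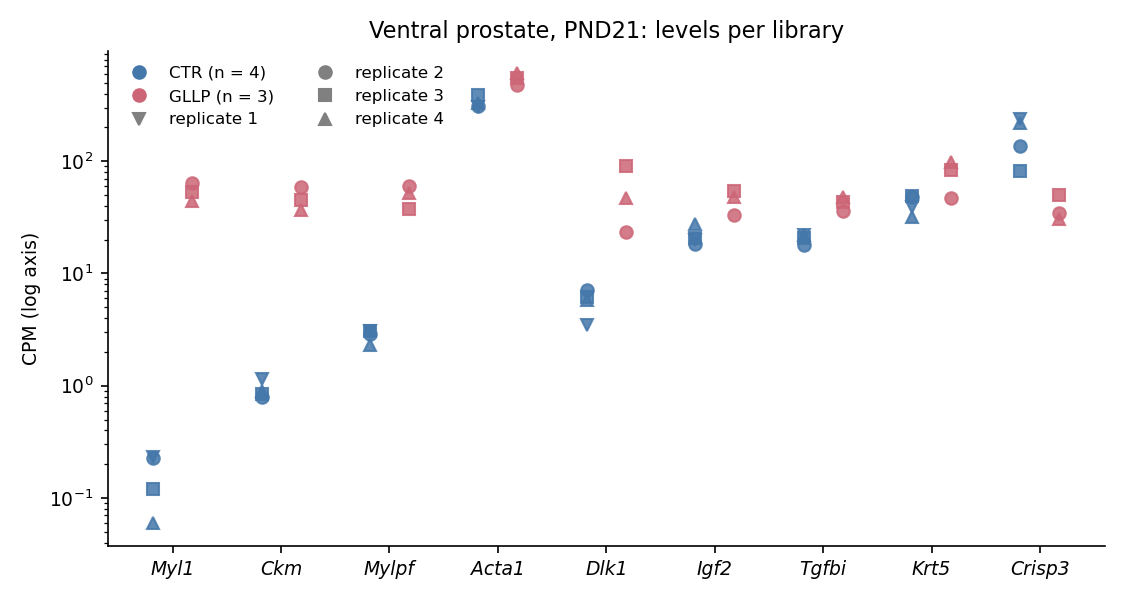
CPM on a log axis at PND21 for 9 genes, with a point for each of the 4 CTR and 3 GLLP libraries and a marker shape for each replicate number. Myl1, Ckm and Mylpf stand above all CTR libraries in each GLLP library, while Crisp3 stands below.

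Among all 14915 genes tested, 150 were higher and 16 lower in GLLP at PND21, and 105 and 7 of these changed at least 2-fold. Of the 150 higher genes, 74 belonged to the striated muscle catalogue (median log2 fold change 3.93) and 76 did not (median 0.98), and none of the 16 lower genes belonged to it. With the catalogue removed before the fit, 4 genes were called, of which Tgfbi, chosen after its values were seen, was the only named one; 16 named genes outside the muscle group then had edgeR adjusted p of 0.0746 to 0.0873. Their fold changes stayed almost as they were (log2 fold change of Crisp3 -2.14 with the catalogue and -2.13 without, of Dlk1 3.24 in both), so what changed was the adjustment, which had fewer small p-values to draw on.

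Imprinted growth genes were among the higher calls outside muscle. Of the 14 tested members of the imprinted list, 5 were called: Dlk1, a regulator of progenitor and adipocyte differentiation, rose from 5.66 ± 1.56 to 53.4 ± 33.6 CPM (log2 fold change 3.24, SE 0.43, adjusted p = 0.0147). The growth factor gene Igf2 rose 2.1-fold, the cell cycle inhibitor Cdkn1c 2.08-fold, Peg3 (also outside the rule) 1.96-fold and Grb10, an adaptor that restrains insulin signalling, 1.56-fold. Adjusted over the list alone, 6 members were higher and 1 lower. The list passed camera (adjusted p = 0.00511) but not with an estimated correlation (adjusted p = 0.484). In the insulin and growth factor list, Igf2 and Grb10 were again the 2 of 27 genes called, 3 were higher and 1 lower when adjusted over the list alone, and the list did not pass camera (adjusted p = 0.608). Of the amino acid starvation genes, 27 of 31 had positive values and Psat1, an enzyme of serine synthesis, rose from 18.7 ± 5.92 to 69.2 ± 27.8 CPM (adjusted p = 0.0298). It was the 1 member called, 3 were called when adjusted over the list alone, and the list passed camera (adjusted p = 0.00728, and adjusted p = 0.484 with an estimated correlation). The list score of GLLP replicate 3 (0.156) lay below that of CTR replicate 4 (0.193).

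Ribosomal protein genes were higher as a list by a small margin. All 43 tested had positive values with a median of 0.48, none was called over all genes and 41 were called when adjusted over the list alone (camera adjusted p = 1.92e-20, and adjusted p = 0.484 with an estimated correlation). Rpl7 stood at 524 ± 14.4 CPM in CTR and 755 ± 87.8 CPM in GLLP. The list holds 54 genes, and those not tested include Rpl10a and Rpl38, with 0 counts in both groups at PND21. Ribosomal protein genes have many near-identical copies, so their counts are uncertain at either age. Endoplasmic reticulum chaperone and secretory machinery genes went the other way: 35 of 36 had negative values, with a median of -0.32 (camera adjusted p = 4.25e-09, and adjusted p = 0.484 with an estimated correlation), and none was called, alone or over all genes. Dnajb9 was at 133 ± 20.6 CPM in CTR and 67.4 ± 28.8 CPM in GLLP.

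Cholesterol and fatty acid synthesis genes were lower (median -0.28, camera adjusted p = 0.00105, and adjusted p = 0.565 with an estimated correlation). The list did not separate the diets, as CTR replicate 3 had the lowest score at -0.378. The GLLP libraries lay at -0.307 to -0.206 and CTR replicates 1, 2 and 4 at 0.0596 to 0.202. Idi1, an enzyme of isoprenoid synthesis, was called (161 ± 11.5 against 114 ± 5.46 CPM, adjusted p = 0.0336), and 8 of 31 were called when adjusted over the list alone, among them the desaturase Scd (log2 fold change -1.06) and Me1 (-0.55). Idi1 was also a call of the androgen-response list, as was Homer2, which rose to 9.63 ± 2.05 from 4.87 ± 0.76 CPM; adjusted over the list alone, 1 of its genes was higher and 2 lower, and as a whole it did not pass camera (adjusted p = 0.377).

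Lists of stroma, basal epithelium and other cell types were higher in GLLP by camera as well, without a called member over all genes. All 9 basal epithelial genes had positive values, with 6 called when adjusted over the list alone: Krt5 stood at 41.8 ± 7.9 CPM in CTR and 76.4 ± 25.9 CPM in GLLP, and Krt14 at 17.3 ± 2.83 and 30.2 ± 9.49 CPM (camera adjusted p = 0.000204). GLLP replicate 2 lay within the CTR range, with a basal score of 0.23 against -0.267 to 0.252 in CTR, and GLLP replicates 3 and 4 lay above it at 0.816 and 0.938. Extracellular matrix genes had 26 of 30 positive values and 13 calls over the list alone, including Serpinh1 and Col6a1 (camera adjusted p = 2.06e-06). The matrix proteases and inhibitors (0.0233), prostate development genes (0.0229), cytokines (0.00417), myeloid (0.00417), T and B cell (0.0479), nerve (0.0226) and endothelial (0.0413) lists also passed camera as higher, with the adjusted p in parentheses. Some GLLP scores lay below CTR replicate 3 for the matrix (0.195 against 0.268), myeloid (0.0989 and 0.309 against 0.342) and T and B cell lists (0.11 against 0.159). For prostate development GLLP replicate 4 (0.0576) lay below CTR replicate 4 (0.0849). In the protease, cytokine, nerve and endothelial lists every GLLP score was above every CTR score. Adjusted over the list alone, 4 genes of the protease list were called (Mmp14, Mmp2, Mmp7 and Mmp23), 2 of the cytokine list (Cxcl1 and Tgfb1) and 1 of the endothelial list (Plvap), all higher, and in the myeloid list 3 were higher and 1 lower. With an estimated correlation the adjusted p was 0.565 for the myeloid list and 0.484 for all the other lists of this paragraph. Urothelial genes had 5 of 5 positive values, and Krt4 was at 0.641 ± 0.447 CPM in CTR and at 4.66, 0.816 and 14.7 CPM in GLLP replicates 2, 3 and 4. Of the list, 2 were called when adjusted over the list alone, but the list did not pass camera (adjusted p = 0.148).

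The secretory genes of the ventral prostate did not pass as a list (camera adjusted p = 0.74), with 0 of 14 called over all genes by edgeR. The prostatein subunit genes Scgb2a1 and Scgb1d2 had log2 fold changes of -0.59 and -0.67, called only when adjusted over the list alone. Luminal (0.441), steroid receptor (0.74), cell cycle (0.803), antioxidant (0.441), oxidative phosphorylation (0.557), adipocyte (0.441), antigen presentation and interferon (0.387), immediate-early (0.821) and erythroid (0.29) lists did not pass either, with camera's adjusted p in parentheses, and Hsd11b2 was the 1 steroid receptor list member called higher. The seminal vesicle list had 2 tested genes and no test. For the secretory, luminal, smooth muscle, cell cycle and steroid receptor lists the median, the mean and the direction of the test differed in sign, and all their medians lay close to 0. Scaling by library size alone moved the median of all genes by 0.14 on the log2 scale, which turned the near-0 medians of the secretory, androgen-response, luminal, steroid receptor and adipocyte lists positive. It also took the median of the endoplasmic reticulum list from -0.316 to -0.179 and that of the cholesterol list from -0.275 to -0.134.

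The lower genes were led by Crisp3, a cysteine-rich secretory protein, at 170 ± 72.7 CPM in CTR and 38.5 ± 10.1 CPM in GLLP (log2 fold change -2.14, SE 0.37, adjusted p = 0.0429). Krt80 was 2.92-fold, Syn1 2.17-fold, the taurine transporter Slc6a6 2.04-fold and the receptor Gpr146 1.8-fold lower. Mboat2, Ccdc9b and Osgin1 were 1.78-fold, 1.77-fold and 1.73-fold lower.

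The number of PND21 calls depended on single libraries and on the tool. Without CTR replicates 1, 2, 3 and 4 in turn it was 62, 63, 75 and 70, without GLLP replicate 3 it was 62, and without GLLP replicate 2 it was 1509; DESeq2 called 972 genes, library size scaling 650 and the joint fit of both ages 40. Of these the lower calls numbered 25 with library size scaling, where the higher calls took most of the rise, 2, 3, 7 and 3 without CTR replicates 1 to 4, 2 without GLLP replicate 3, 714 without GLLP replicate 2, 301 with DESeq2 and 0 in the joint fit. The 9 named lower genes each lost their call in 4 to 6 of the 7 fits with a library left out, the 7 higher ones named by the rule outside muscle in 3 to 6, and the 10 named muscle genes in 0, all with edgeR.

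At PND540 no gene differed between the diets with edgeR. Of 14767 genes tested, 123 (0.833%) had an unadjusted p under 0.05 and the smallest adjusted p was 0.914. That share is below the 0.05 that tests without any effect give on average. DESeq2 called 2 genes, Fuom and Marf1, and limma voom with sample weights called 0. The 5 genes with the smallest p did not pass: Fuom was at 2.37 ± 1.51 CPM in CTR (SD, n = 5) and 0.251 ± 0.158 CPM in GLLP (SD, n = 4), Marf1 at 0.554 ± 0.498 and 5.06 ± 2.68 CPM, Cyp2c11 at 1.87 ± 2.36 and 0.23 ± 0.123 CPM, Grm6 at 0.857 ± 0.528 and 0.234 ± 0.104 CPM, and Hprt1 at 0.178 ± 0.133 and 4.64 ± 8.4 CPM. With CTR replicate 5 included, the biological coefficient of variation was 46.2%, against 19.6% at PND21, and changes of 2-fold were recovered in 2.99% of simulated cases. Without CTR replicate 5 the count of calls was 0 as well, and 110 of 14638 genes had an unadjusted p under 0.05.

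At the level of lists, 18 of 29 passed camera at PND540 and none did with an estimated correlation (adjusted p = 0.55 for most). Ribosomal protein genes were lower in GLLP, with 52 of 54 negative values and a median of -0.52 (camera adjusted p = 7.85e-10, and adjusted p = 0.55 with an estimated correlation). Their score was 1.23 in CTR replicate 5, -0.511 to -0.0839 in the other CTR libraries and -0.562 to -0.246 in GLLP. The ranges without CTR replicate 5 thus overlapped, and the median of -0.52 rests largely on that library. The list still passed camera as lower without it (adjusted p = 0.000239, preset correlation). Extracellular matrix (median 0.50), adipocyte (0.75) and cholesterol synthesis genes (0.36) were higher, and antigen presentation genes (-0.54), T and B cell genes (-0.46) and cell cycle genes (-0.21) were lower, each past camera and each with adjusted p = 0.55 with an estimated correlation. CTR replicate 1 had low scores for the matrix (-1.29, other CTR libraries -0.549 to 0.835) and adipocyte lists (-2.35, others -0.108 to 1.71). The GLLP scores, -0.724 to 1.17 and 0.626 to 1.8, overlapped those of the other CTR libraries. The diets also overlapped for antigen presentation (CTR -0.656 to 0.58, GLLP -0.783 to 0.112) and T and B cell genes (-0.52 to 0.789, -0.789 to -0.138). The same held for cell cycle (CTR -0.334 to 0.375, GLLP -0.634 to 0.159) and cholesterol synthesis genes (-0.6 to 0.659, -0.0423 to 1.02). CTR replicates 1 and 5 had the highest CTR scores for antigen presentation (0.58, 0.504) and T and B cell genes (0.789, 0.392). With all libraries 10 lists passed camera as higher, against 5 without CTR replicate 1 and 4 without CTR replicate 4. Leaving out any other library gave 6 to 11, so the dependence was not particular to CTR replicate 1. No member of any list was called, alone or over all genes.

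**Figure D3:**
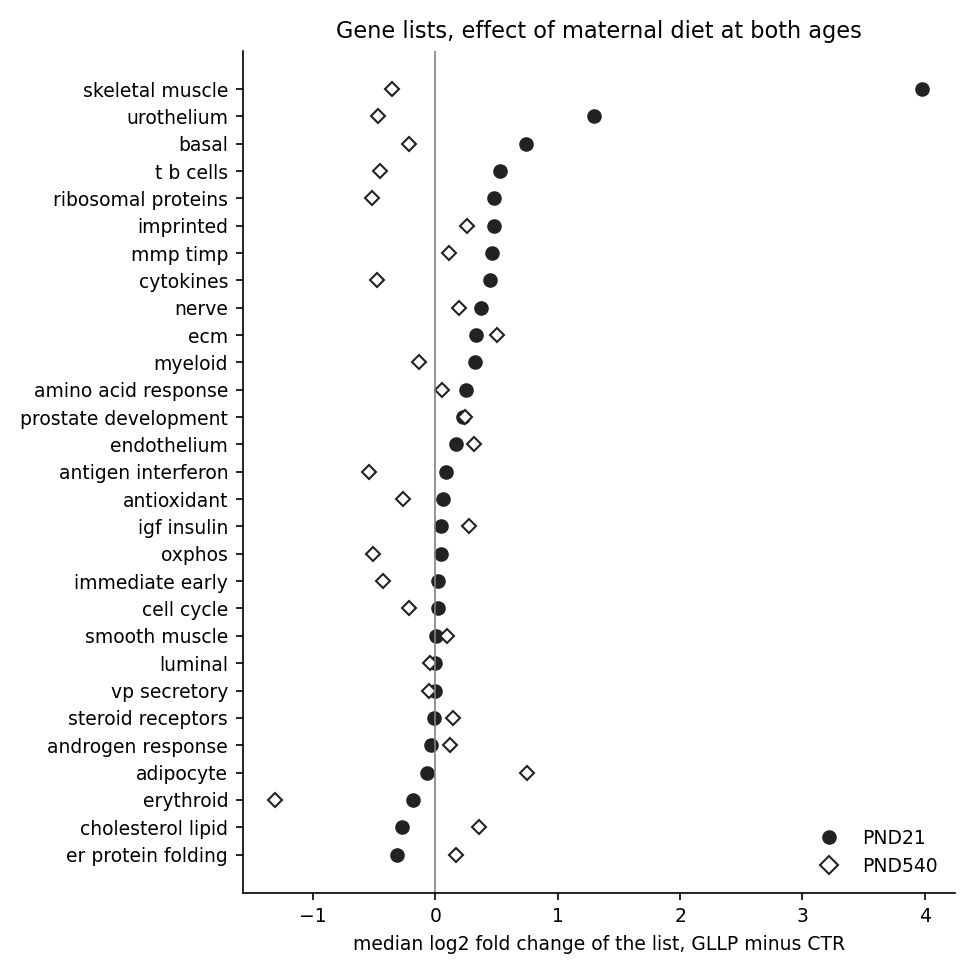
Median log2 fold change (GLLP minus CTR) of 29 gene lists at PND21 (filled circles) and PND540 (open diamonds), ordered by the PND21 value. The skeletal muscle list stands at 3.98 at PND21 and at -0.354 at PND540.

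Between PND21 and PND540 in CTR, cell cycle and matrix genes were lower, and antigen presentation and T and B cell genes higher, at the later age. Of 51 cell cycle and DNA replication genes, 48 were lower at PND540 with a median log2 fold change of -3.9 (camera adjusted p = 5.45e-28, and adjusted p = 0.176 with an estimated correlation): Bub1b fell 33.5-fold, Ccna2 23.9-fold and Tk1 21.1-fold. Of 31 extracellular matrix genes, 25 were lower, with Col1a1 going from 1930 ± 364 CPM (SD, n = 4) to 39.5 ± 27.1 CPM (SD, n = 5) and the elastin gene Eln from 339 ± 49 to 15.8 ± 8.98 CPM (camera adjusted p = 8.26e-11, and adjusted p = 0.676 with an estimated correlation). In addition 6 of 13 imprinted genes were lower, among them Dlk1, Igf2 (7.08-fold) and Grb10 (3.95-fold), with adjusted p = 0.000153 in camera and adjusted p = 0.176 with an estimated correlation.

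Antigen presentation and interferon genes were higher at PND540, 22 of 34 of them called, and RT1-Da, a class II antigen presentation gene, rose 9.29-fold (camera adjusted p = 7.48e-07, and adjusted p = 0.676 with an estimated correlation). Likewise 8 of 18 T and B cell genes were called higher, among them Cd4 (7.05-fold) and Cd3e (8.67-fold), with adjusted p = 0.00395 in camera and adjusted p = 0.676 with an estimated correlation. The myeloid list (13 higher and 5 lower of 24, adjusted p = 0.105) and the cytokine list (7 higher and 1 lower of 20, adjusted p = 0.488) did not pass camera. Smooth muscle genes were lower, 7 of 14 called, with Acta2 4.69-fold and Myh11 4.04-fold lower (camera adjusted p = 0.00521, and adjusted p = 0.676 with an estimated correlation). Of the secretory genes, the prostatein gene Scgb2a2 rose from 307 ± 38.8 to 20500 ± 8140 CPM. Probasin (Pbsn) was at 169 ± 64.3 and 14.7 ± 17 CPM, and that list did not pass camera (adjusted p = 0.918), its median of 0.32 standing against a downward direction of the test.

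In all, 2336 genes were higher and 1781 lower at PND540 in CTR, of 13510 tested, and without CTR replicate 5 the calls numbered 6574. Library size scaling moved the median of all genes by -0.11 on the log2 scale. The age comparison carries the difference between the tables. Genes that every cell uses stood at or near 0 at PND21 and were abundant at PND540. Fth1, the ferritin heavy chain, Rpl23a, Rpl10a, Rpl38, Prelid1 and Hist1h4b had 0 counts in all 4 CTR libraries at PND21. At PND540 Fth1 stood at 1480 ± 594 CPM in CTR. For scale, 3 counts over the PND21 group would be 0.025 CPM by library size without TMM. Fau, Rps29 and Rpl39 had 1, 2 and 1 counts over the 4 libraries. The higher genes with the smallest p also stood far lower at PND21: Ptma was at 3.91 ± 0.0615 CPM and 530 ± 126 CPM, the cytoplasmic actin Actg1 at 14.8 ± 2.25 and 531 ± 67.5 CPM, Epb41l1 at 0.557 ± 0.113 and 228 ± 23.5 CPM, and Man2b2 at 3.44 ± 0.19 and 218 ± 34 CPM. Ugt1a9, Saa4 and Adh6 had 0 counts in all CTR libraries at PND540, and Klk1, Mxd3, Fsd1, Adamts19, Ccno, Adh4, Stat4, Gstm3 and Sh3bgrl2 were under 1 CPM there. In contrast Actb (1950 and 2030 CPM), Gapdh (228 and 230 CPM) and Tpt1 (2120 and 1890 CPM), chosen after their values were seen, stood at similar levels in both tables. These CPM values were scaled by library size without TMM, a scale on which Fth1 stood at 1380 CPM at PND540. In CTR, 97 higher calls had no counts at PND21 and 16 lower calls had none at PND540. The antigen presentation list holds 2 genes with 0 counts in CTR in 1 table, and the endothelial list 1. The ribosomal protein list, 29 of 50 called higher, holds 3 such genes. Ribosomal protein genes have many near-identical copies, so their counts are uncertain. That list passed camera (adjusted p = 8.64e-11, and adjusted p = 0.676 with an estimated correlation). Cholesterol synthesis (0.00395), endoplasmic reticulum (0.00849), endothelial (0.0178) and skeletal muscle (0.0425) lists passed as lower and the immediate-early list (0.0425) as higher, with camera's adjusted p in parentheses and adjusted p of 0.676 to 0.726 with an estimated correlation.

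In GLLP, 2611 genes were higher and 2341 lower at PND540, of 13694 tested; with library size scaling the split was 1965 higher and 2916 lower, as that scaling moved the median of all genes by -0.17 on the log2 scale. Periostin (Postn), a matrix protein, went from 181 ± 7.67 CPM (SD, n = 3) to 6.26 ± 0.89 CPM (SD, n = 4), and the replication gene Gins2 from 60.6 ± 9.33 to 2.52 ± 0.338 CPM. Dlk1 fell from 61.4 ± 38.3 to 0.0283 ± 0.0567 CPM and Myh4 from 201 ± 93.3 to 0.143 ± 0.163 CPM. Chtop fell 9.33-fold in GLLP and 8.96-fold in CTR. Among the genes the rule named, those under 3 CPM in 1 table were again Fth1, Rpl23a, Rps29, Fau, Rpl10a, Rpl38, Prelid1, Hist1h4b, Rpl39, Gpx4, Ftl1, Rps19 and Rps18 at PND21 and Klk1, Ugt1a9, Fsd1, Saa4, Adh6 and Mxd3 at PND540. Gins2, Dlk1 and Myh4 were also under 3 CPM at PND540, so a difference between the tables is not excluded for them.

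The genes called for a diet effect that differed between the ages were mostly muscle genes, though the splits described further on leave chance open. In total 13 genes had a diet effect that was lower at PND540 than at PND21, and none the reverse, of 14178 tested; 733 had an unadjusted p under 0.05. The differences in log2 fold change were -8.28 for Myh4 (SE 1.41, adjusted p = 0.0331), -8.17 for Myl1 (SE 1.01, adjusted p = 0.0012), -6.31 for Tnni2, -6.01 for Ckm, -5.66 for Actn3, -5.54 for Mybpc1, -5.31 for Eef1a2, a translation factor of muscle and nerve, and -4.71 for Mylpf. All 22 skeletal muscle genes were negative (camera adjusted p = 7.45e-49, and adjusted p = 0.000416 with an estimated correlation), and 11 other lists passed camera without holding under an estimated correlation. Only 15 genes of the skeletal muscle list passed the filter at PND540 alone. For the others the negative sign largely restates the PND21 difference. A difference between the tables cancels in this contrast only if it multiplies a gene's counts by a fixed factor and the gene is counted in both. A gene with hardly any counts in 1 table has a poorly measured diet effect there. Myh4, at 0.143 ± 0.163 CPM in GLLP at PND540, is such a gene. With the muscle catalogue removed edgeR called 0 genes, with 668 at an unadjusted p under 0.05. On all genes DESeq2 called 46 and limma voom with sample weights 35, and the count was 8 without CTR PND21 replicate 2 or 3, 7 without GLLP PND21 replicate 2 and 8 without GLLP PND21 replicate 3.

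No gene was called at both ages, among 12680 genes tested at both, since none was called at PND540. At an unadjusted p under 0.01, 579 genes were higher at PND21 and 2 at PND540, and 274 and 2 were lower, with 0 shared in either direction. Chance would give 0.0913 shared higher and 0.0432 shared lower genes, so an overlap of 0 decides nothing. Across genes, which are not independent replicates, the diet effects at both ages had a Pearson correlation of -0.22 and a Spearman correlation of -0.31. From mean log2 CPM the values were -0.267 and -0.341, and 28 and 32 of 100 regroupings of the diet labels within each age, the real one included, gave values as far from 0. Of the genes called at PND21 and tested at PND540, 42 (41.6%) had the same sign at both ages.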

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

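The splits of the samples for the PND21 diet effect, the age effects and the interaction were planned, but the number drawn for the interaction was raised after a first result was seen; the tests on the muscle genes, on CTR replicate 5 at PND540 and the splits for the PND540 diet effect were chosen only after the result was seen.

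In the diet by age comparison, 13 genes had a diet effect that differed between the ages by the interaction test: Mylpf (-4.71), Tnni2 (-6.31), Ckm (-6.01), Actn3 (-5.66), Eef1a2 (-5.31), Mybpc1 (-5.54), Myl1 (-8.17), Eno3 (-2.56), Myh3 (-5.70), Actn2 (-3.66), Cox6a2 (-5.48), Myh4 (-8.28) and Them5 (-6.71), each value a difference in log2 fold change. Eno3, Myh3, Actn2, Cox6a2 and Them5 fall outside the rule for named genes and were chosen after their values were seen. Most of the 13 are genes of skeletal muscle.

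These muscle transcripts were higher in every GLLP library at PND21, and 95.5% of the tested skeletal muscle list separated the diets, against 17.1% of all tested genes and 5.71% by chance, both in either direction. A difference in scaling moves all genes alike and is argued against. The lower quartile of the list's log2 fold changes lay 2.17 above the median of all genes. Library size scaling alone shifted that median by only 0.14. This measure replaced a count of calls under that scaling, which could not have come out the other way. The replacement was set after the list's values were seen, so its outcome was known as well. The share of 95.5% restates the pattern, so striated muscle dissected along with the gland and expression of muscle genes within the GLLP gland could each give it and cannot be told apart here. A single muscle source is argued against for the 76 higher calls outside the muscle catalogue as a set, though not for 19 of them. For these 19 the excess over CTR in GLLP replicate 2 was above the mean excess of the other GLLP libraries. The same held for 65 of the 74 calls inside the catalogue. The log2 ratio of the excess in GLLP replicate 2 to that mean had a median of -0.843 outside the catalogue (middle 50% from -1.08 to -0.102). Inside it the median was 0.598 (0.381 to 0.937). The catalogue holds 169 genes, and was written after the calls were seen; skeletal actin (Acta1) stood at 331 CPM in CTR as well.

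CTR replicate 5 at PND540 had a median correlation of 0.851 with the other libraries, whose lowest was 0.956. Loss of reads from long genes could account for part of this. The deviation of CTR replicate 5 had a Spearman's rho of -0.439 with gene length across genes, which are not independent replicates, against -0.269 to 0.25 in the other libraries. The lengths were genomic lengths from GRCr8, introns included, and not the lengths of the transcripts. Length was known for 87.9% of the genes, and the baseline of the deviation was changed to leave this library out after values were seen. Blood is argued against, as haemoglobin genes held 0.173% of its counts, although this was above the 0.00554% to 0.0254% of the others. A tissue wholly in place of the gland is argued against, as secretory genes held 7.72% of its counts, within the 3.69% to 16.8% of the others; this measure replaced the median deviation of the 12 genes (-0.597) after that value was seen, and 3 of them lay below all other libraries (Msmb at 0.241 against 13.3 to 275 CPM, Pbsn at 0.0344 against 0.632 to 34.2 CPM, Acpp at 8.9 against 39.2 to 63.7 CPM). A partial mixture, an animal with a diseased gland and degraded RNA stay open, and no biological explanation was tested.

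Whether chance alone gives such counts was examined by refitting other splits. For the diet effect at PND21, 1 of 35 splits gave as many calls, the real one with 166, and the highest other gave 1. Only 35 splits are possible, so 1 of 35 is the smallest share they can give. Chance is argued against but not excluded. For the age effects 1 of 100 splits in CTR (4117 calls; highest other 1525) and 1 of 35 in GLLP (4952; highest other 0) gave as many; the split with 1525 calls moved CTR replicate 5 at PND540 to the PND21 side, a structure of the samples. For the diet effect at PND540, edgeR called 0 genes (123 at an unadjusted p under 0.05, 2 calls with DESeq2), so 100 of 100 splits gave as many by construction and the count of splits decides nothing; the highest gave 8. For the interaction 4 of 100 splits gave at least 13 calls, the real one included; the highest other gave 39, a split that keeps the real PND21 groups and points to a structure of the samples. The 3 of 99 other splits have an exact 95% binomial interval of 0.629% to 8.6%, so that share is close to the level of 0.05. A smaller first draw had given a share of 0.05, which does not exclude chance. A split that keeps the real PND21 groups also keeps the diet effect at PND21, so such splits are not free of an effect. The share therefore cannot decide, and the splits leave chance open for the interaction.

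Dixon's test at the 95% level also flagged single libraries far from the rest of their group, in 14 of 125 groups of values. Chance gives about 1 in 20 groups, or 6.25, for normally distributed values, which CPM near 0 are not. CTR replicate 1 at PND21 had a median correlation of 0.97 with the other libraries, the others of its group 0.975 to 0.976. CTR replicate 5 at PND540 had list scores of -0.757 for androgen-responsive genes, 0.66 for antioxidant genes and 1.23 for ribosomal proteins, and 1.79 CPM of Grm6. GLLP replicate 3 at PND540 had list scores of -0.462 for basal and 0.725 for endoplasmic reticulum genes. At PND21, CTR replicate 2 had 0.113 CPM of Myh8, and CTR replicate 1 had 0.202 CPM of Mb and 87.1 CPM of Gpr146. Myh8 and Mb had only 4 and 8 counts over the CTR group, so these 2 flags rest on a few reads. At PND540, CTR replicate 4 had 6.07 CPM of Cyp2c11, GLLP replicate 2 had 0.389 CPM of Grm6 and GLLP replicate 1 had 17.2 CPM of Hprt1.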

How the results depend on the processing

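Limma voom with sample weights, the overlap of the ages with DESeq2 and the fits without muscle or mitochondrial genes were chosen after seeing the data; the cause of each change below was not tested unless given. No named gene changed sign under the alternatives run. With library size alone 5 list medians near 0 at PND21 turned positive and the GLLP age calls went from 2611 higher and 2341 lower to 1965 and 2916. The erythroid list at PND540 went from downward (camera adjusted p = 0.313) to upward (adjusted p = 0.047) without CTR replicate 5. The 166 PND21 diet calls became 650 with library size alone, 972 with DESeq2, 40 in the joint fit, 3490 with limma voom and 4 without the muscle catalogue, where fewer genes carry the adjustment; leaving out a library gave 62 to 1509. The PND540 diet effect had 0 calls with edgeR (123 genes at an unadjusted p under 0.05), 2 with DESeq2, 0 with limma voom and 0 to 0 without any library. The age effect in CTR had 4117 calls, 7368 with limma voom and 3040 to 6574 with a library left out, the highest without CTR PND540 replicate 5; in GLLP 4952 became 3434 to 5239. The interaction had 13 calls, 46 with DESeq2, 35 with limma voom, 0 without the muscle catalogue and 7 to 16 with a library left out. The number of lists passing was 15 at PND21 (1 with an estimated correlation, 1 with fry, 12 to 17 with a library left out), 18 at PND540 (0, 0, and 12 to 19), 12 for age in CTR, 4 higher and 8 lower (0 with an estimated correlation, 13 with fry, 7 higher and 6 lower, and 10 to 13) and 12 for the interaction (1, 1, and 11 to 16). The overlap of the ages was 0 with edgeR, at an unadjusted p under 0.01, with library size alone, a filter at 1 CPM, DESeq2 and limma voom. With so few genes at PND540 this could hardly come out otherwise. At an unadjusted p under 0.01 chance gives 0.0913 shared higher and 0.0432 shared lower genes. Replicate numbers did not pair the samples: same-numbered deviations correlated at -0.14, 0.15 and -0.12 at PND21 and between -0.17 and 0.30 at PND540, and not every sample correlated best with its own number. With the replicate block the calls were 27 for the PND21 diet effect, 0 at PND540, 6012 and 3814 for age in CTR and GLLP, and 10 for the interaction. Among values of named genes at PND21 under the alternatives, 981 kept their side of the threshold, 141 fell below it and 154 rose above it. At 28748604 to 39161666 counts per library, genes with a few counts per library stay undecided; the biological coefficient of variation was 46.2% at PND540.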

Other observations

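The test of the diet effect against the age effect had its prediction fixed before its result was seen; the other values here were picked after they were seen.

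Beside the muscle genes, the urothelial genes Upk1b and Krt4 had higher means in GLLP at PND21, carried largely by GLLP replicate 4. They stood at 0.473 ± 0.221 and 0.641 ± 0.447 CPM in CTR (SD, n = 4) and at 2.45 ± 2.05 and 6.73 ± 7.18 CPM in GLLP (SD, n = 3), with edgeR adjusted p of 0.0895 and 0.12. Neither passed over all genes. In GLLP replicates 2, 3 and 4 Upk1b was at 1.09, 1.45 and 4.81 CPM and Krt4 at 4.66, 0.816 and 14.7 CPM, and CTR replicate 1 reached 1.21 CPM of Krt4.

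A less advanced gland in the GLLP offspring is a hypothesis that would give diet effects at PND21 opposite to the age effects in CTR. Across 14040 genes outside the muscle catalogue, with separate CTR libraries in each effect, Pearson's r over 6 halvings of the controls ran from -0.0663 to 0.0149. Leaving out CTR PND540 replicate 5 gave -0.108 to -0.0352. With all controls shared r was 0.0168 and the covariance 0.0109. Unchanged groups simulated against the same controls gave an r of 0.233 and a covariance of 0.0384. The simulated groups held no age effect, and a large age effect lowers r by itself, so only the covariances can be compared. These values may be consistent with a weak opposite relation or with none; genes are not independent replicates, the age effect carries the difference between the tables, and the hypothesis stays undecided.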
